A study of Homo sapiens with 6 samples.

How the data were processed

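RNA from LA1-55n, a human neuroblastoma cell line, was measured on 6 Affymetrix Human Gene 2.0 ST arrays. Per the labels, 3 arrays came from cells carrying a doxycycline-inducible hairpin against GFP (shGFP) and 3 from cells carrying an inducible hairpin against glycine decarboxylase (shGLDC99). Both populations received 0.5 µg/ml doxycycline for 7 days. The replicates carry the letters a, b and c. Beyond describing them as independent samples, the series design text does not say how they were separated, so the p-values measure the spread between these samples.

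The deposited values are given per probe set and array, and they were read as log2 intensity. Their log base is not stated. The highest value, 13.28, exceeds 11.09, the natural log of the highest 16-bit intensity, which excludes natural log and log10 of scanner intensities; log2 is therefore inferred, and every fold below rests on it. Per the submitters' processing notes, Partek was used, with its version not given. The background correction, normalization and summarisation are not given in the sources used here. Array medians lay between 4.28 and 4.33, and no further normalization was applied. The number of arrays limits the precision.

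The table holds 31135 probe sets. Of these, 15098 carried 1 gene symbol in the platform annotation, 0 carried several, and 16037 had no gene name here. All 15098 named probe sets matched the reference gene table by Entrez ID, with 0 symbols updated. The named probe sets covered 14779 genes, of which 256 had more than 1 probe set, and each such gene was represented by the probe set with the highest mean over the 6 arrays. No filter on dim probe sets was applied. The platform annotation is incomplete in these names: MYCN, which the rule for named genes included, had no named probe set, and only 38 genes with an SLC symbol were measured. No genome build is stated for the array, so no coordinates are given; the reference served only for names and for which genes lie next to each other.

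Differences are shGLDC99 minus shGFP on the log2 scale. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, constant prior variance, no covariates), and p-values were adjusted by the Benjamini-Hochberg method over all 14779 genes. A gene is said to have risen, fallen or changed where its adjusted p was under 0.05. Standard errors are the moderated ones of that model. Data were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

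A set of 46 gene lists with 1059 genes was written from general knowledge, of which 645 genes were measured. The lists share some members, so their tests are not independent of each other. The 43 lists with at least 4 measured genes were tested with camera in limma (two-sided, preset inter-gene correlation 0.01, adjusted over the lists). Histones and amino acid transporters had 0 measured genes and antigen presentation had 3, so these lists were not tested. Each list was also tested with camera using an estimated correlation and with fry, whose p-value asks whether a set moves, on balance, 1 way and does not compare it with other genes. For each list the number of genes past the threshold is given over all genes and adjusted over the list alone.

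The comparison, the tests, the 46 lists, the rule for named genes and all but the last of the alternatives given below were chosen before the data were examined. The rule named the glycine cleavage genes GLDC, AMT, GCSH and DLD, and MYCN. It also named the 12 largest rises and the 12 largest falls among changed genes whose groups did not overlap and whose mean in the higher group was at or above the median gene level of 5.09. From each described list it took up to 4 genes with the smallest adjusted p. Genes named outside this rule, to complete short counts, were chosen after their values were seen. The lists for Schwann and glial cells, fibroblasts, endothelium, leukocytes, epithelium and mesenchymal neuroblastoma cells serve as markers of other cells that a culture could hold.

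The model was tested on simulated data with 14779 genes and 200 changed genes in 3 against 3 arrays. It recovered 35% of the genes changed by 0.5 on the log2 scale and 87% of those changed by 1. Of 127 genes called, 5 were unchanged, and 0 were called when no change was simulated. With 1 list shifted, 1 list was called, and with none shifted 0 were called. The simulated genes were drawn independently of each other, so this does not test list calls where genes move together.

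The alternatives were quantile normalization again, centring each array on its median, leaving out the dimmest 40% of genes, averaging the probe sets of a gene, the replicate letter as a block, and leaving out each array in turn. Others were an intensity trend in the prior variance, array quality weights, an unmoderated linear model, an adjusted p of 0.01, treat against a fold of 1.2, and all 31135 probe sets. Lists of REST targets, YAP and TEAD targets and heat shock genes were added after some of those genes had been seen, as was the recalculation of each called list under those alternatives that were planned for the number of lists called.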

Results

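Gene expression was measured in LA1-55n neuroblastoma cells with an induced hairpin against GFP (shGFP) or against glycine decarboxylase (shGLDC99), with 3 arrays in each group. The comparison asks which transcripts differ when a hairpin against GLDC takes the place of the control hairpin. Arrays of the same group correlated at 0.993 to 0.994 over all 31135 probe sets, and arrays of different groups at 0.988 to 0.990. Over the 14779 genes, the first principal component held 42.8% of the variance.

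The transcript of GLDC, the decarboxylase of the mitochondrial glycine cleavage system, was lower in all 3 shGLDC99 arrays than in any shGFP array. Its level was 7.86 ± 0.0474 (SD, n = 3) on the log2 scale in shGFP cells and 5.85 ± 0.180 (SD, n = 3) in shGLDC99 cells. The log2 difference was -2.00 ± 0.10 (SE), or 4.01-fold lower, with 24.9% of the control level left (limma adjusted p = 0.00101). It was the largest fall among the genes tested. An exact two-sided permutation test on the 6 values gave p = 0.1, the smallest that 3 against 3 allows.

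The other parts of the glycine cleavage system were not past the threshold over all genes. DLD, the dihydrolipoamide dehydrogenase shared with other mitochondrial complexes, differed by 0.26 (adjusted p = 0.0532), with all shGLDC99 arrays above all shGFP arrays. AMT, the aminomethyltransferase, differed by 0.03 (adjusted p = 0.846). GCSH, the lipoyl carrier protein, differed by 0.27 (adjusted p = 0.429), with shGLDC99 array a at 5.29 against 4.65 and 4.63 in the other two. Of the 4 genes, 0 rose and 1 fell. Adjusted over the list alone, 1 rose (DLD) and 1 fell. Over all genes, 1 rose with quantile normalization again, without the dimmest 40% of genes, with an intensity trend in the prior variance or without moderation. With the replicate block or any 1 array left out, 0 rose. The list was not called by camera (adjusted p = 0.951).

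**Figure D1:**
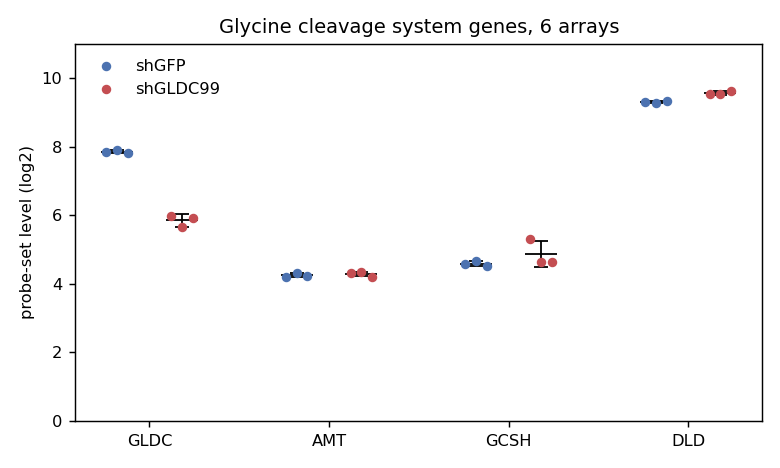
Probe-set level (log2) of GLDC, AMT, GCSH and DLD in each of the 6 arrays, with the mean and SD of each group (n = 3). GLDC was lower in every shGLDC99 array, with group means of 7.86 in shGFP and 5.85 in shGLDC99.

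Beyond GLDC, 19 of 25 measured genes of DNA replication and 14 of 32 of mitosis fell in shGLDC99 cells, while 7 of 19 genes of neuronal differentiation and 5 of 20 targets of the stress factor ATF4 rose. Camera called these 4 lists with its preset correlation but not with an estimated one (adjusted p = 0.0617, 0.0617, 0.278 and 0.131 with an estimated correlation). RELN, a secreted guidance protein of the developing brain, rose by 1.88 ± 0.115 (SE) on the log2 scale, or 3.68-fold, from a shGFP level of 4.57. PCDH9, a protocadherin, fell by 1.87 ± 0.0981 (SE), or 3.65-fold lower, to a shGLDC99 level of 4.60. These lower levels of RELN and PCDH9 lie below the median gene level and are not shown to exceed background. The exact size of both differences is therefore uncertain. REST, the repressor of neuronal genes in other cell types, fell by 1.39 ± 0.103 (SE), or 2.61-fold lower.

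Of 14779 genes tested, 1259 changed, 550 of them higher and 709 lower in shGLDC99 cells. Most changes were small, with a median absolute log2 difference of 0.46 among the changed genes, and 53 genes (29 higher, 24 lower) changed at least 2-fold. The groups did not overlap for 4559 genes (30.8%, where chance gives 10%). The median over all genes was -0.01. Leaving out any 1 of the 6 arrays (shGFP a, b or c, or shGLDC99 a, b or c) left 461 to 546 changed genes.

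The 12 largest rises also included SCG2 and CCND2. SCG2, a granin stored in dense-core vesicles, rose by 1.43 ± 0.0631 (SE), or 2.70-fold. CLU, a secreted chaperone, rose by 1.31, RCAN2, a calcineurin inhibitor, by 1.29, and DUSP4, a phosphatase that inactivates MAP kinases, by 1.49. CCND2, a D-type cyclin, rose by 1.71, although a second and dimmer probe set of the gene gave 0.34. The shGFP levels of CCND2 (4.31) and of GPRIN3 (4.98) lay below the median gene level. They are not shown to exceed background, so the exact size of these rises is uncertain. GPRIN3 (1.31), PLPPR1 (1.12), BTBD8 (1.29) and the heparan and dermatan sulphate modifying enzymes HS6ST3 (1.16) and UST (1.24) also rose. TSPYL6 rose by 1.29; it lies within ACYP2, which was not measured.

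The 12 largest falls also included ADCY8 and RORB. ADCY8, a calcium-stimulated adenylyl cyclase, fell by 1.68, and RORB, a nuclear receptor of neurons, fell by 1.55. FN1, which encodes fibronectin, fell by 1.43 and HMCN1, an extracellular matrix protein, fell by 1.45. JAG1, a ligand of Notch receptors, was 2.30-fold lower and PLS3, an actin-bundling protein, fell by 1.22. AKNAD1 (-1.27) and NELL1 (-1.23) fell as well. The probe set of MIR490 fell by 1.46. It overlaps CHRM2, which was not measured, and whether it reads the microRNA or its host transcript was not determined. The shGLDC99 levels of ADCY8 (3.97), MIR490 (4.18), NELL1 (4.39) and HMCN1 (4.80) lay below the median gene level. They are not shown to exceed background, so the exact size of these falls is uncertain.

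**Figure D2:**
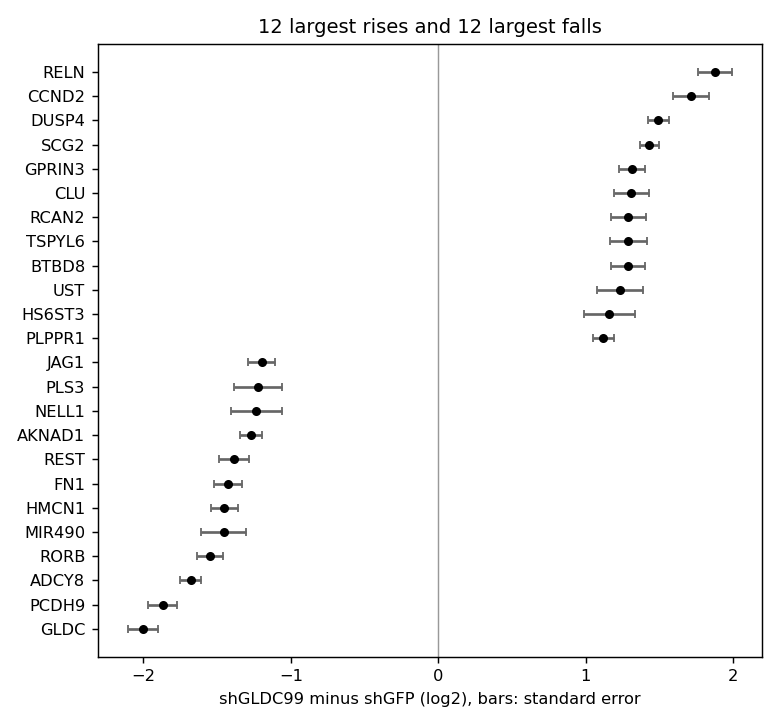
Log2 difference (shGLDC99 minus shGFP) of the 12 largest rises and 12 largest falls among changed genes, with standard errors (n = 3 per group). The values run from -2.00 for GLDC to 1.88 for RELN.

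Most of the measured genes of DNA replication fell. Of 25 measured, 19 fell, 0 rose and 6 were not past the threshold; adjusted over the list alone, 22 fell. UHRF1, which maintains DNA methylation at replication forks, fell by 0.81. The replicative helicase subunit MCM5 fell by 0.77, its partner GINS4 by 0.73 and the origin-firing factor MCM10 by 0.54. The list median was -0.45 (camera adjusted p = 4.0e-15; adjusted p = 0.0617 with an estimated correlation).

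Mitosis genes were lower in all 32 measured, of which 14 fell past the threshold, 0 rose and 18 were not past it; adjusted over the list alone, 25 fell. KIF20A, a kinesin of the cleavage furrow, fell by 0.53 and TOP2A, the topoisomerase that untangles chromosomes, fell by 0.46. CCNA2 fell by 0.44 and MKI67, the proliferation marker, fell by 0.40. The median was -0.30 (camera adjusted p = 1.69e-13; adjusted p = 0.0617 with an estimated correlation). Without any 1 of the 6 arrays, 11 to 13 replication genes and 2 to 7 mitosis genes fell. Mitosis falls numbered 24 of 31 without the dimmest 40% of genes and 26 of 32 with an intensity trend in the prior variance.

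Lists of DNA repair and of pyrimidine synthesis also had lower medians, of -0.27 and -0.18. Of 13 repair genes 5 fell, 0 rose and 8 were not past the threshold; adjusted over the list alone, 8 fell. Among them BARD1, the partner of BRCA1, fell by 0.84, the mismatch repair protein MSH6 by 0.43, the exonuclease EXO1 by 0.42 and the checkpoint kinase CHEK1 by 0.40. The helicase BRIP1, chosen after its value was seen, fell by 0.27 (list camera adjusted p = 7.8e-06; adjusted p = 0.198 with an estimated correlation). Of 12 pyrimidine and deoxynucleotide genes 2 fell, TYMS by 0.32 and UCK2 by 0.30, and 0 rose; adjusted over the list alone, 6 fell and 1 rose. That list had a camera adjusted p of 0.00527 (adjusted p = 0.462 with an estimated correlation). Without any 1 of the 6 arrays, 1 to 3 repair genes and 0 pyrimidine genes fell; with an intensity trend in the prior variance, 9 and 6 fell, and 5 pyrimidine genes fell without the dimmest 40% of genes.

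Of 10 measured regulators of entry into the cell cycle, 8 were lower, 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0662). CDK6 and CCND1 each fell by 0.60, RBL1 by 0.59 and CDK2, chosen after its value was seen, by 0.55, whereas CCND2 rose. The 11 measured p53 targets did not include CDKN1A or MDM2. Of these 11, 1 rose, TP53INP1 by 0.57, and 0 fell. Adjusted over the list alone, 2 rose and 0 fell (camera adjusted p = 0.951). Of 25 listed apoptosis genes 17 were measured, with no caspase among them. Of these 17, 1 fell, BCL2 by 0.53, over all genes and adjusted over the list alone (camera adjusted p = 0.618).

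Targets of ATF4, the factor of the integrated stress response, were higher in 19 of 20 measured genes. Of these 5 rose, 0 fell and 15 were not past the threshold; adjusted over the list alone, 9 rose. DDIT4, an inhibitor of mTORC1, rose by 0.82, the tryptophanyl-tRNA synthetase WARS1 by 0.60, the pseudokinase TRIB3 by 0.57 and asparagine synthetase (ASNS) by 0.39. The seryl-tRNA synthetase SARS1, chosen after its value was seen, rose by 0.36. The median was 0.15 (camera adjusted p = 7.8e-06; adjusted p = 0.131 with an estimated correlation). Without any 1 of the 6 arrays, 2 to 4 of these genes rose, and with an intensity trend in the prior variance 10 or, without the dimmest 40% of genes, 8 of 17 rose. In the list of the unfolded protein response of the endoplasmic reticulum, 10 of 20 genes were measured. Of these, 0 changed over all genes or adjusted over the list alone (camera adjusted p = 0.825).

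Genes of neuronal differentiation were higher in 16 of 19 measured. Of these 7 rose, 1 fell and 11 were not past the threshold; adjusted over the list alone, 11 rose and 1 fell. STMN4, a microtubule regulator of neurites, rose by 1.05, the axonal adhesion protein CNTN1 by 0.70 and the dendritic marker MAP2 by 0.43, whereas GFRA2, the neurturin co-receptor, fell by 1.09. The median was 0.30 (camera adjusted p = 1.48e-05; adjusted p = 0.278 with an estimated correlation). Leaving out any 1 of the 6 arrays left 3 to 5 rises.

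Among 11 genes of catecholamine handling and vesicle storage, 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0627). Besides SCG2, MAOB rose by 0.49 and CHGB by 0.41, and GCH1, which opens the synthesis of the cofactor of tyrosine hydroxylase, fell by 0.68. Of 22 genes of axon guidance and adhesion 3 fell and 0 rose; adjusted over the list alone, 5 fell and 0 rose (camera adjusted p = 0.0627). These were PCDH9, the ephrin receptor EPHA5 (-0.58) and the guidance ligand SLIT3 (-0.47).

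Some markers of both neuroblastoma cell identities changed. Neither list was called by camera, while fry called both as lower (fry adjusted p = 0.0361 for adrenergic and 0.0129 for mesenchymal). Of 23 adrenergic identity factors, which define the sympathetic lineage, 6 fell and 3 rose; adjusted over the list alone, 7 fell and 4 rose (camera adjusted p = 0.584). ISL1 fell by 1.09 (by 0.71 when its probe sets were averaged), LMO3 by 0.99, TBX2 by 0.60 and GATA2 by 0.56. Chosen after their values were seen, SATB1 (-0.50) and GATA3 (-0.48) also fell, and RET (0.65), EYA1 (0.29) and INSM1 (0.26) rose. Of 30 markers of the mesenchymal, substrate-adherent identity 5 fell and 2 rose; adjusted over the list alone, 7 fell and 2 rose (camera adjusted p = 0.160). Besides FN1, YAP1, a growth coactivator, fell by 0.97, and the Notch receptors NOTCH3 and NOTCH2 fell by 0.83 and 0.60. Chosen after their values were seen, vimentin (VIM, -0.37) also fell, and IRF2 (0.95) and FOSL2 (0.48) rose. Leaving out any 1 of the 6 arrays left 2 to 5 falls and 0 or 1 rise in the adrenergic list and 3 to 5 falls and 0 or 1 rise in the mesenchymal list.

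The other signalling lists were not called by camera. Of 20 Notch, Wnt and hedgehog genes 1 fell, the Notch target NRARP (-0.52), and 0 rose; adjusted over the list alone, 2 fell and 1 rose (camera adjusted p = 0.898). Of 10 TGF-beta and BMP genes 2 fell, the inhibitors SMAD6 (-0.96) and SMAD7 (-0.44), also adjusted over the list alone (camera adjusted p = 0.618). Of 18 MAP kinase and early response genes 3 rose and 3 fell; adjusted over the list alone, 3 rose and 5 fell (camera adjusted p = 0.732). These included the rises of DUSP4 and SPRY2 (0.90), which both restrain the pathway, and the falls of EGR1 (-0.71) and CCND1. Chosen after their values were seen, ETV5 (0.46) also rose and FOSB (-0.43) fell. Of 21 retinoid and HOX genes 1 rose, HOXD13 (0.59), and 1 fell, CRABP2 (-0.60); adjusted over the list alone, 4 rose and 3 fell (camera adjusted p = 0.832).

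The metabolic lists next to glycine cleavage were not called by camera. Of 16 genes of serine, glycine and folate metabolism 1 rose, SFXN3, a mitochondrial serine carrier (0.74), and 1 fell, methionine synthase MTR (-0.28); adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.853). PHGDH, the first enzyme of serine synthesis, differed by -0.24 (adjusted p = 0.0581). Of 16 purine genes 2 fell, GMPS (-0.28) and PPAT (-0.27), and 0 rose, also adjusted over the list alone (camera adjusted p = 0.825). Of 6 lipoylation genes 1 rose, the lipoyl synthase LIAS (0.27), and 0 fell, also adjusted over the list alone (camera adjusted p = 0.732).

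Lipid and carbon metabolism lists were not called by camera either, though fry called glycolysis as lower (fry adjusted p = 0.0129). Of 17 cholesterol genes 1 rose, STARD4 (0.30), and 2 fell, the regulator SREBF2 (-0.47) and ACAT2 (-0.29); adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.825). Of 17 fatty acid genes 1 rose, the acyl-CoA ligase ACSL4 (0.54), and 1 fell, the synthase FASN (-0.41); adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.576). Of 24 listed glycolysis genes 8 were measured, of which 1 rose, HK1 (0.29), and 1 fell, HK2 (-0.52). Adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.549). Of 26 listed genes of the citrate cycle 10 were measured and 0 changed, also adjusted over the list alone (camera adjusted p = 0.618).

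The lists of lysosomes and of the respiratory chain had medians above 0, of 0.23 and 0.12. Of 15 lysosome and autophagy genes 2 rose, the autophagy receptor SQSTM1 by 0.46 and cathepsin Z (CTSZ) by 0.30, and 0 fell; adjusted over the list alone, 6 rose and 0 fell. The camera adjusted p was 0.00155 (adjusted p = 0.422 with an estimated correlation). Of 40 listed nuclear-encoded genes of oxidative phosphorylation 12 were measured, all UQCR, COX or CYC1 genes, so other parts of the chain were not covered. Of these 12, 2 rose, UQCRB by 0.47 and COX7C by 0.34, and 0 fell. Adjusted over the list alone, 3 rose and 0 fell. The camera adjusted p was 0.00925 (adjusted p = 0.462 with an estimated correlation). Leaving out any 1 of the 6 arrays left 0 or 1 rise in each of these lists. With an intensity trend in the prior variance 4 and 3 rose, and without the dimmest 40% of genes 5 of 13 and 3 of 12.

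**Figure D3:**
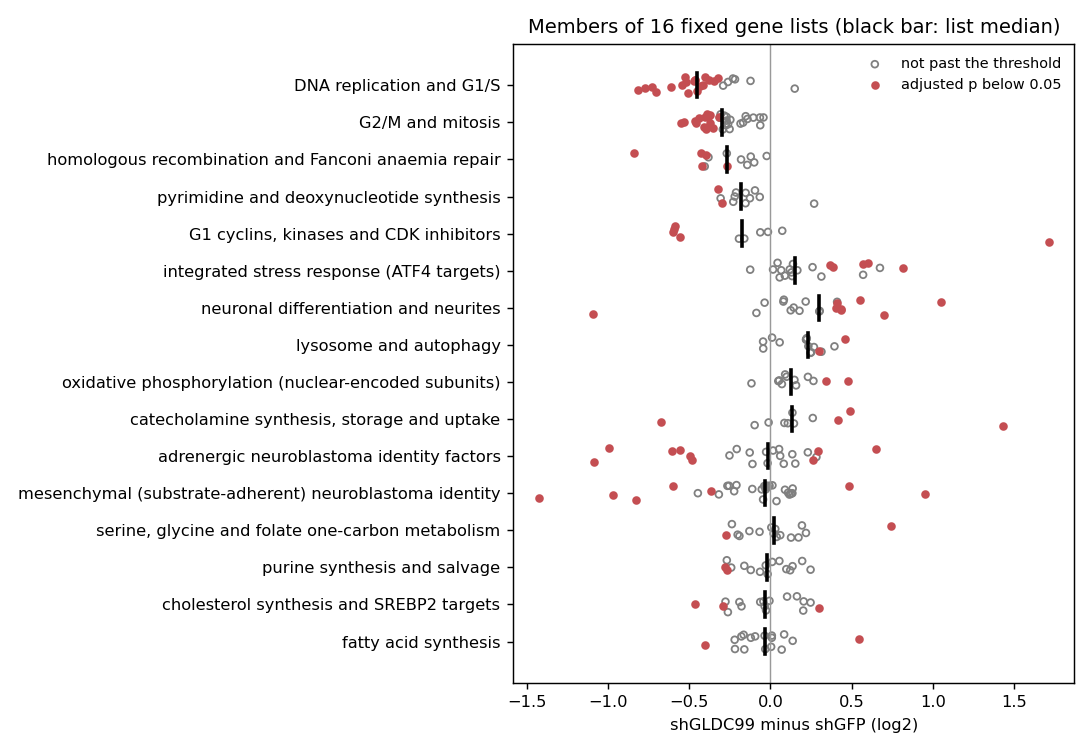
Log2 difference (shGLDC99 minus shGFP) of each measured gene in 16 of the lists, with filled points past an adjusted p of 0.05 and bars at the list medians. Replication (-0.45) and mitosis (-0.30) genes lie to the left, and neuronal differentiation genes (0.30) to the right.

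Lists of protein synthesis, stress and immune genes were not called by camera, though fry called ribosome biogenesis as lower (fry adjusted p = 0.0180). Of 20 ribosome biogenesis genes 1 fell, fibrillarin (FBL, -0.43), and 0 rose (camera adjusted p = 0.126), and of 9 genes of small RNA handling 1 fell, LIN28B (-0.27), and 0 rose (camera adjusted p = 0.853); both counts were the same adjusted over the list alone. Over all genes and adjusted over the list alone, 0 changed among 19 ribosomal proteins (camera adjusted p = 0.732), 27 mitochondrial ribosomal proteins (0.549), 13 NRF2 and glutathione genes (0.259) and 7 neighbours, partners or relatives of MYCN (0.618). MYCN itself was not measured. Of 23 interferon genes 3 fell, HERC5 (-0.63), BST2 (-0.39) and IFIT1 (-0.34, at levels of 2.09 and 1.75), and 1 rose, the kinase EIF2AK2 (0.36); adjusted over the list alone, 3 fell and 2 rose (camera adjusted p = 0.898). Of 17 hypoxia genes 3 fell and 1 rose; adjusted over the list alone, 4 fell and 2 rose (camera adjusted p = 0.898). These were HK2, LOX (-0.42) and BNIP3L (-0.30) against EGLN3 (0.49). Of 17 inflammatory and senescence-associated genes 1 fell, IGFBP5 (-0.95), and 0 rose, also adjusted over the list alone (camera adjusted p = 0.928).

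Markers of other cell types gave no list call. Of 10 fibroblast markers 1 rose, LUM (0.52, from a dim level of 3.48), and of 9 Schwann and glial markers 1 rose, L1CAM (0.55), a gene that the neuronal list also holds; 0 of either fell, and both counts were the same adjusted over the list alone (camera adjusted p = 0.463 and 0.825). Over all genes and adjusted over the list alone, 0 changed among 11 epithelial (camera adjusted p = 0.732), 9 endothelial (0.898) and 7 leukocyte markers (0.832). Of 13 extracellular matrix genes 3 fell and 2 rose; adjusted over the list alone, 4 fell and 5 rose (camera adjusted p = 0.951). Besides FN1 and LOX among the falls, the protease inhibitor TIMP3 (0.92) and LUM rose, and FBN2, chosen after its value was seen, fell by 0.39.

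In all, camera called 8 of the 43 lists with its preset correlation, 0 with an estimated correlation, and fry called 16. Beyond the 8, fry called lists that included axon guidance, cell cycle entry, ribosome biogenesis, mesenchymal, glycolysis and adrenergic genes, all lower. It also called the catecholamine list, as higher (fry adjusted p from 0.0116 to 0.0361 over these lists). A list described above as not called was not called by camera. The median, mean and test differed in sign for the unfolded protein response, Schwann and glial, retinoid and HOX, interferon, inflammatory, glycine cleavage and p53 lists. The series holds 1 hairpin against GLDC and 1 cell population per group, so the comparison is between these populations. The small counts in the lists that were not called often lost genes when 1 array was left out; the purine list, for example, then had 0 falls. Of the changed genes named above, BST2, CTSZ, EGLN3, ETV5, FBN2, FOSB, IFIT1, LMO3, LUM and YAP1 lay below the median gene level of 5.09 in both groups and are not shown to exceed background. Others lay below it in 1 group, such as RELN, CCND2 and GPRIN3 in shGFP and PCDH9, ADCY8, MIR490, HMCN1 and NELL1 in shGLDC99. The exact size of their differences is uncertain.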

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

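The tests of a second hairpin, of other splits of the arrays and of the mesenchymal share were chosen only after the result was seen; the lists of REST and of YAP and TEAD targets were written after some members had been seen, and the tests leave those out.

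Signal appeared in probe sets with no gene name here, which the report does not use. Of all 31135 probe sets fitted together with limma, 572 unnamed ones were past an adjusted p of 0.05, 306 higher and 266 lower. Only those with a higher group mean at or above the median gene level of 5.09 were ranked by size. The largest rises among these were probe set 17086386 (log2 difference 2.30) and probe set 16924636 (2.16). The largest falls among these were probe set 17059355 (-2.41) and probe set 16780133 (-1.52). Their lower group means, from 3.72 to 3.89, lay below the median gene level and are not shown to exceed background. The exact size of these differences is therefore uncertain.

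Of 25 DNA replication genes 19 fell, and of 32 mitosis genes 14 fell, with a median of -0.37 over all 57 and an adjusted p of 0.0617 for each list with an estimated correlation. A shift between the arrays that depends on level is argued against, since 0 of 10000 random lists matched on level had a median as low, the lowest being -0.15. A difference in copy number between the populations is argued against by 437 neighbouring genes, whose median was -0.0233 (95% bootstrap interval -0.0551 to -0.00952) where -0.19 or lower was needed. An effect of the hairpin or the cell population other than loss of GLDC cannot be told apart from GLDC loss, because the number of GLDC hairpins was 1. Slower proliferation on loss of GLDC may account for the pattern, but it stays a hypothesis, and the same limit of 1 hairpin holds for the patterns below.

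REST fell, and 7 of 19 genes of neuronal differentiation rose while 1 fell (list adjusted p = 0.278 with an estimated correlation). Among 33 measured REST targets, 24 had not been seen before. The median of the 24 was 0.14, 17 were higher, and 12 of 10000 matched random lists had a median as high. This would follow from release of REST targets. The random lists drew genes independently of each other, so the count does not allow for targets that move together. They were matched on level only, so a rise of neuronal genes for another reason would give the same result as release. The test cannot tell these apart. Counted as seen were members of the fixed lists and changed genes with large differences. The choice of the 24 therefore depended partly on the outcome. It left out both targets that fell, NPAS4 and SYT4, and also SCG2. Over all 33 the median was 0.17, and 1 of 10000 matched lists had a median as high, but these hold genes that prompted the test. Of all 33, 5 rose (SCG2, CHGB, L1CAM, VGF by 0.57 and UNC80 by 0.52) and 2 fell, NPAS4 (-0.98) and SYT4 (-0.61), so release may hold for part of the targets only. A shift that depends on level is argued against for the neuronal list, as 0 of 10000 matched lists had a median as high as its 0.30, the highest being 0.19. REST protein was not measured here.

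YAP1, NOTCH2, NOTCH3, FN1 and the YAP partners TEAD2 (-1.08) and TEAD3 (-0.86) fell, whereas TEAD1 was -0.02 (adjusted p = 0.897). WWTR1, the related coactivator TAZ, was -0.03 (limma adjusted p = 0.925). Both YAP1 and WWTR1 lay below the median gene level in both groups and are not shown to exceed background. Among 14 YAP and TEAD targets not seen before, TEAD1 itself included, the median was -0.08, and 955 of 10000 matched lists had a median as low. Over all 19 measured targets the median was -0.06, and 1531 of 10000 matched lists had a median as low. Of the 19, 2 fell, CCND1 (-0.60) and FSTL1 (-0.49), and 1 rose, DOCK5 (0.42). The bound written beforehand, 5% of lists, counts the 14 against lower YAP output, and the 19 would count against it too. That bound was set aside after the value for the 14 was seen. The bootstrap interval of their median, -0.192 to 0.0133, spans the 5th percentile of the matched medians, -0.10, so 14 genes leave it open. For a lower share of mesenchymal cells, 14 markers at or above the median gene level were used, among them FN1, NOTCH2 and NOTCH3 of the pattern itself. Their median was -0.0830 (interval -0.367 to 0.0118), short of the bound of -0.71 set from FN1. That bound was also set aside after the value was seen: it takes these markers to come from mesenchymal cells alone, and their level in neuroblastic cells was not measured here, so a lower share cannot be told apart from a change within the cells.

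The count of 1259 changed genes was compared with other splits of the 6 arrays. Only 10 splits exist, too few for a share under 0.05: the number calling as many genes was 1, the real one, and the highest of the others called 0.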

How the results depend on the processing

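The recalculation of each called list was chosen after seeing the data; the other alternatives were planned. The GLDC level stayed past the threshold under each of the 14 alternatives run for it (not the stricter p, treat or all probe sets), with a log2 difference from -2.07 to -1.90 and an adjusted p from 8.81e-08 to 0.0273. The number of genes changed, 1259 (550 higher, 709 lower), was 2221 (969 and 1252) without the dimmest 40% of genes, and 2438 (1088 and 1350) with an intensity trend in the prior variance. It was 275 at an adjusted p of 0.01 and 121 with treat against a fold of 1.2, which are stricter criteria by construction. Leaving out 1 array gave 461 to 546 changed genes (207 to 240 higher, 238 to 327 lower), with fewer samples in the model. The cause of the remaining moves was not tested. Quantile normalization gave 1389, centring 1205 and the unmoderated linear model 1016. The number of lists called, 8 with the preset correlation, was 0 with an estimated correlation and 16 with fry, and the adjusted p with an estimated correlation was 0.0617 for replication and for mitosis, 0.131 for ATF4 targets, 0.198 for repair, 0.278 for neuronal differentiation, 0.422 for lysosome, and 0.462 for pyrimidine and for oxidative phosphorylation. Of 188 named genes, 99 were past the threshold, and 0 changed sign in any alternative while past it. The number of arrays, 6, limits what could be called.

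With the replicate letter as a block (replicate block), 229 genes changed (103 higher, 126 lower), 224 of them shared with the 1259. No pairing of the arrays by letter was seen over all genes, which does not exclude pairing that affects few genes. The deviations of arrays with the same letter correlated at -0.0119, 0.0182 and -0.00106, and 2 of 6 arrays were closest to their own letter. Replication then had 6 genes that fell and mitosis 0, with the same log2 differences (medians -0.45 and -0.30), and 55 named genes were no longer past the threshold. Of the 8 lists, 8 stayed called by camera with the block at its preset correlation. Without the block, 0 were called with an estimated correlation.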

Other observations

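The heat shock list and the gene families here were chosen after values had been seen. Chaperones of the heat shock response held 4 falls and 0 rises among 16 measured genes. HSPB1, a small chaperone, fell by 0.69, and the cochaperone BAG2 fell by 0.48. HSPA1A (-0.65) and HSPA1B (-0.66) also fell, but these copies are nearly identical and their probe sets may read each other. The list median was -0.07, and 1217 of 10000 matched random lists had a median as low, so the list as a whole did not stand apart.

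Families of genes sharing a symbol stem, 218 in all, were tested in both directions with an exact hypergeometric test. The MCM stem had 7 of 11 genes that fell and 0 that rose (adjusted p = 6.9e-05 for the falls). The KIF stem, mostly kinesins, had 11 of 40 that fell and 2 that rose (adjusted p = 0.000403 for the falls). The 7 MCM genes belong to the replication list, and KIF20A, KIF2C, KIF23 and KIF11 to the mitosis list, so these are not separate results. The hypergeometric test also takes the genes as independent of each other. The protocadherin beta cluster (PCDHB) had 6 of 19 genes that rose and 1 that fell (adjusted p = 0.00673). Its members are close copies on the same chromosome arm, so their probe sets are not independent of each other. Nucleoporins (NUP) had 6 of 24 that fell (adjusted p = 0.0833) and DUSP phosphatases 5 of 24 that rose (adjusted p = 0.142), which did not pass.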
